A study of Mus musculus with 6 samples.

How the data were processed

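RNA was measured in neurospheres from 6 CD1 mice, an outbred stock, on 6 Affymetrix Mouse Gene 2.0 ST arrays. Per the labels' protocols, pregnant females received 2 intraperitoneal injections a day, of PBS or of 0.5 mg/kg MG, starting on gestational day 12 and ending at birth. Cells from the subependymal region of their 2-month-old offspring were grown for 7 days with EGF and FGF2, and biotinylated cDNA was made from the total RNA with the WT PLUS kit. The sample titles and the tissue label call the cultures primary neurospheres, whereas the sample descriptions call them secondary; they are called neurospheres here. The labels do not give the animals' sex, nor whether the 3 animals of a group shared a mother. The p-values of single genes set the difference between groups against the spread among the 3 samples within each group. All p-values may be too small if animals of a group shared a mother, and a difference between litters cannot be separated from the injections.

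The values deposited by the authors are on a log2 scale, 1 per probe set and array, and lie between 0.73 and 13.81. Partek 6.6 is named per the submitters' processing notes, while the background correction, the normalisation and the summarisation are not given in the sources used here. The log2 scale was inferred from the range of the deposited values. The median over all 41345 probe sets lay between 5.25 and 5.42 on the 6 arrays. For arrays, the number of samples limits the precision. The median standard error of a gene's log2 difference was 0.15, and its 95% confidence interval reached a median of 0.35 to either side.

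Probe sets were named through the platform's annotation, with symbols updated through the RefSeq gene table of GRCm38.p6. Of the probe sets, 23521 named 1 gene, 1814 named several and 16010 were unnamed here. The genes tested were the 22180 with a probe set of their own. For the 1082 genes with several probe sets, the one with the highest mean over all 6 arrays was used. No gene was left out for being dim. To describe levels, a reference was taken after the data were seen, as the 95th percentile of the mean levels of 1394 olfactory and vomeronasal receptor genes, which was 5.02 on the log2 scale. 13725 genes were above it in both groups. No fold is given for a gene below it in both groups. The genome build used for the array values is not given in the sources used here, so no coordinates are printed.

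MG was compared with PBS, 3 arrays against 3, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, two-sided). Adjusted p-values are Benjamini-Hochberg values over the genes tested, and the threshold was 0.05. A looser count took genes with an unadjusted p under 0.05 and at least 1.5-fold. Sets of genes were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 32 lists. A list of Xist and Y-linked genes served only as a check of the animals. Of the 881 listed symbols, 803 were tested. Camera compares a list with all other genes, so its direction can differ from the sign of the list's mean. At the preset correlation its p-value rests on the spread between genes. It does not measure how far a list's mean varies between animals. Camera with an estimated correlation and fry were run beside it. Per-array list values are means of the members after each gene was centred on its mean over the 6 arrays. Principal components were taken from the genes tested, and figures were drawn with matplotlib 3.10.9.

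The comparison, the gene lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule took, per direction, 10 genes past the adjusted threshold with no overlap between groups. Where too few passed, it was filled by the smallest unadjusted p among genes past the looser count with no overlap, leaving out gene models, small RNAs and receptor families. It also took the 4 members with the smallest p in the direction of each called list, members of other lists past the adjusted threshold, and Glo1, Hagh, Park7 and Akr1a1. Akr1b3, also on the rule, was not analysed here because no probe set was matched to it alone.

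The alternatives were a filter on dim genes, all probe sets, averaged probe sets, quantile normalisation, median centring, other variance moderation, array weights, the replicate number as a block, other set tests, the sex-linked genes left out, and each array left out in turn. Leaving out both arrays numbered 3 was added after the principal components were seen, and the estimated correlation with arrays left out after the list calls were seen. The steps were tested on simulated data in 20 runs on 22180 genes, with 50 genes per fold and noise independent between genes. In the simulation, 16.7% of genes changed 1.5-fold were recovered, 86.5% at 2-fold, 98.8% at 3-fold and 99.2% at 4-fold. The mean was 9.5 false calls per run. The simulation changed 200 genes at once, which eases the adjusted threshold, and gave the arrays no shared structure. On the real arrays the first principal component held 44.1% of the variance, so these shares do not give the power of the real comparison. A simulated shift of 0.15 in the mitosis list was called in 17 of 20 runs. On the real arrays the estimated correlation within this list was 0.887, not 0 as simulated, so the result does not carry over to them.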

Results

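Neurospheres are floating colonies grown from neural stem and progenitor cells, here from the subventricular zone, a niche along the lateral ventricles where neurons are born in adult life. Expression was measured in cultures from 3 offspring of PBS-injected mothers and 3 offspring of mothers injected with MG, read here as methylglyoxal from the title of the series. Methylglyoxal is a reactive by-product of glycolysis that glyoxalase 1, encoded by Glo1, helps to clear. The title names a Glo1 and methylglyoxal pathway, maternal diabetes and neural stem cells, and the comparison asks how expression in adult offspring cells differed after the prenatal injections. The Y-linked genes Eif2s3y (log2 values 9.0 to 9.62), Kdm5d (7.98 to 8.08) and Uty (7.97 to 8.38) were bright on all 6 arrays. Xist, the RNA of the inactive X chromosome, lay between 3.40 and 3.82, below the reference level of 5.02 on every array. These values argue against a difference in sex between the groups.

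Genes of DNA replication and mitosis set the arrays numbered 3 of both groups apart from the other 4. The mean of the 35 replication and S phase genes, relative to the average of the 6 arrays, was 0.46 in PBS replicate 3 and 0.44 in MG replicate 3, and between -0.39 and -0.13 on the other arrays. The 38 mitosis genes stood at 0.35 and 0.34 on the arrays numbered 3, and between -0.36 and -0.08 elsewhere. Genes of glycolysis and lactate went the other way, at -0.40 and -0.41 against 0.02 to 0.38. Astrocyte genes were at -0.28 and -0.25 there, and between -0.06 and 0.24 on the other arrays. The first principal component held 44.1% of the variance. PBS replicate 3 had a score of 21.0 on it and MG replicate 3 one of 37.6, while the other arrays scored from -21.3 to -9.86.

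**Figure D1:**
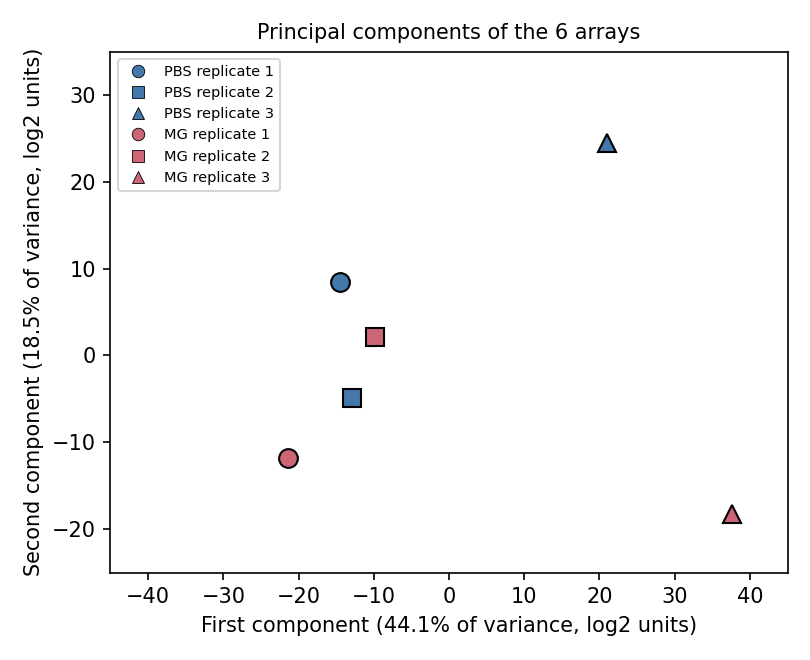
Scores of the 6 arrays on the first (x axis, 44.1% of the variance) and second (y axis, 18.5%) principal components, in log2 units, with colour for the group and shape for the replicate. The arrays numbered 3 of both groups sit at 21.0 and 37.6 on the x axis, and the other 4 sit below 0.

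Among genes above the reference level in both groups, the naming rule gave Adcy2, Kcnj16, Zfp992 and Trim21, with higher means after MG. It also gave Ifna4, S100a10 and Aldh1a3, with lower means, of which Ifna4, like Zfp992, belongs to a family of closely similar genes. None of the 22180 genes passed limma's moderated test after Benjamini-Hochberg adjustment, so the values of these genes are given as measured and not as changes. Ifna4 had the smallest adjusted p, 0.241, and the next smallest was 0.9998. At an unadjusted p under 0.05 there were 712 genes, 3.21% of those tested, where chance alone gives 1109. Of these, 101 differed at least 1.5-fold, 52 with higher and 49 with lower means after MG, and 31 of the 101 were above the reference level in both groups. The groups did not overlap in 1629 genes, 7.34%, where chance gives 10%. The count of 101 was 24 without dim genes and 239 without MG replicate 1. The ordinary linear model without moderation gave 0 adjusted calls and 41 in the looser count.

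Adcy2, an adenylyl cyclase that makes cyclic AMP, had a mean of 6.97 ± 0.35 (SD, n = 3) in PBS and 8.09 ± 0.18 (SD, n = 3) in MG, a log2 difference of 1.11 with a standard error of 0.19. Its values differed 2.16-fold, with an unadjusted p of 0.000383 and an adjusted p of 0.9998 in limma. Kcnj16, an inwardly rectifying potassium channel subunit, went from 7.06 ± 0.31 to 7.89 ± 0.14, a log2 difference of 0.83 with a standard error of 0.17. Trim21, a ubiquitin ligase that binds antibodies inside cells, had means of 6.41 ± 0.15 and 7.10 ± 0.29, a log2 difference of 0.69 (standard error 0.17). The zinc finger gene Zfp992 had means of 6.91 ± 0.30 and 7.72 ± 0.17, a log2 difference of 0.81 (standard error 0.18). Cacna1g, a T-type calcium channel subunit, was above the reference level only in MG, at 5.94 ± 0.46 against 4.92 ± 0.28. The unadjusted p of Kcnj16, Zfp992, Cacna1g and Trim21 lay between 0.00135 and 0.00366. Scgb2b6, Asb4, Stfa3, Lce1e and Prl3d3 had higher means after MG but were below the reference level in both groups.

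S100a10, the S100 family member that partners annexin A2, had a lower mean after MG. It stood at 10.4 ± 0.33 (SD, n = 3) in PBS and 9.23 ± 0.12 (SD, n = 3) in MG, a log2 difference of -1.15 with a standard error of 0.18, or 2.22-fold. Aldh1a3, an enzyme of retinoic acid synthesis, had means of 7.64 ± 0.20 and 6.61 ± 0.38, a log2 difference of -1.03 (standard error 0.21). The interferon gene Ifna4 had means of 7.20 ± 0.20 and 5.43 ± 0.31, a log2 difference of -1.77 (standard error 0.18). The other 12 interferon alpha genes had a median log2 difference of 0.01 and a range from -0.31 to 0.49. Their levels are not given here, so this range does not show whether a fall in them could have been seen. The unadjusted p was 1.09e-05 for Ifna4, 0.000201 for S100a10 and 0.00105 for Aldh1a3, and the adjusted p of S100a10 and Aldh1a3 in limma was 0.9998. Usp17le was above the reference level only in PBS, at 5.59 ± 0.13 against 4.63 ± 0.20. Zfp982, Klrb1, Serpinb6c, Rps15a-ps2, Magea3 and Dnah7a had lower means after MG and were below the reference level in both groups. Among the named genes, at least Ifna4, Usp17le, Zfp992, Zfp982, Scgb2b6, Stfa3, Magea3 and Prl3d3 belong to families of closely similar genes. Their values are uncertain because near-identical copies can share a probe set's signal.

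**Figure D2:**
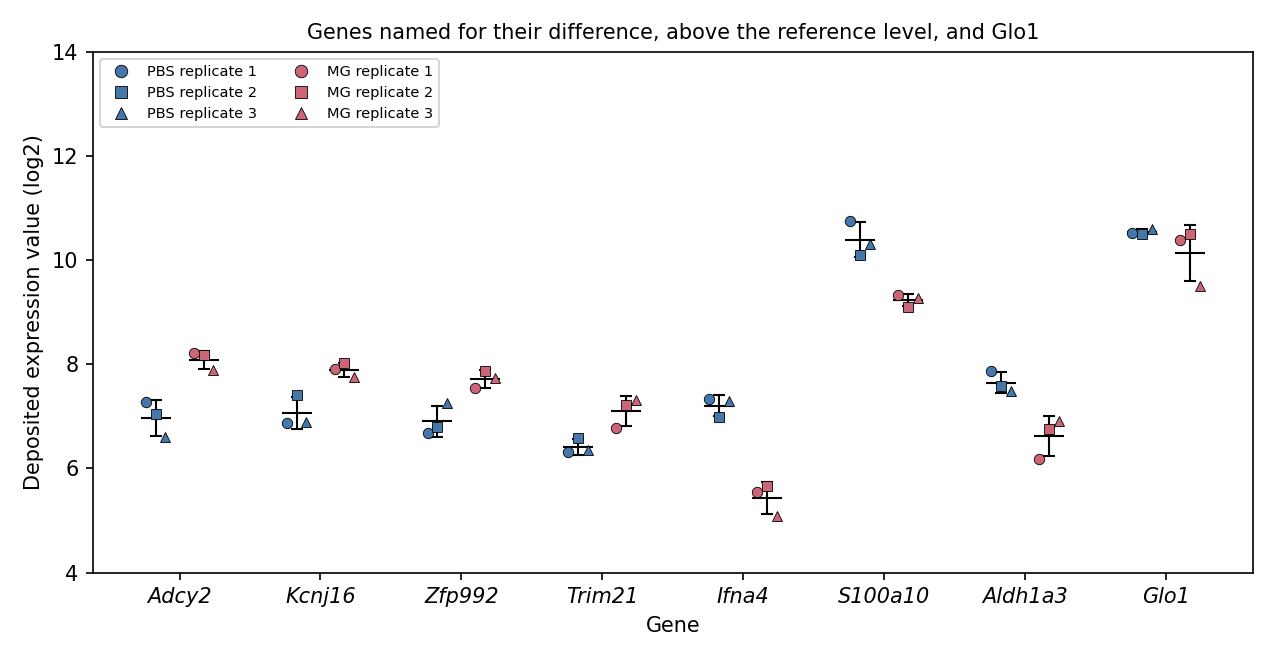
Deposited log2 expression values (y axis) of 7 genes named for their difference and above the reference level in both groups, and of Glo1 (x axis), with 1 point per array, colour for the group, shape for the replicate, and bars for the mean ± SD of 3 arrays. In MG replicate 3, Glo1 sits at 9.51 while the other 5 arrays lie between 10.39 and 10.59.

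Glo1 was low in 1 of the 3 MG cultures and close to the PBS level in the other two. Its values were 10.51, 10.50 and 10.59 in PBS, and 10.39, 10.50 and 9.51 in MG replicates 1, 2 and 3. The log2 difference was -0.40 with a standard error of 0.25 and a 95% confidence interval from -0.97 to 0.16. The adjusted p in limma was 0.9998. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows, because all 3 MG values, that of replicate 2 narrowly, lay under the lowest PBS value. Without MG replicate 3 the log2 difference was -0.09 with a standard error of 0.12. Hagh, which encodes glyoxalase 2, differed by -0.10, Park7, which encodes DJ-1, by 0.11, and the aldehyde reductase gene Akr1a1 by -0.02. Of 21 genes of methylglyoxal and aldehyde detoxification, 11 had higher and 10 lower means after MG, and the list was not called (adjusted p = 0.891). None of its members passed adjusted over the list alone.

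Most Notch pathway genes had higher means after MG, and the list was called in the preset camera test, but not with an estimated correlation or by fry. Of 29 genes, 24 had higher and 5 lower means, with a mean log2 difference of 0.12 and an adjusted p of 0.0409 (camera, Benjamini-Hochberg over 32 lists). The adjusted p was 0.994 with an estimated correlation and 0.9998 with fry. The members named were the Delta family gene Dll3 (log2 difference 0.35) and the fringe glycosyltransferase gene Mfng (0.34). The repressor genes Hey2 (0.34) and Hes5 (0.35), which are Notch targets, were also named. No member passed over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05. Per array, the list stood at -0.10, -0.03 and -0.05 in PBS, and at -0.03, 0.03 and 0.18 in MG. Of the 10 ways to split the 6 arrays into 3 and 3, the real groups called the fewest lists, 2. The other splits called between 3 and 12. The call was lost without PBS replicate 1 (mean 0.10, adjusted p = 0.129), MG replicate 2 (0.13, 0.0641) or MG replicate 3 (0.06, 0.518), and without both arrays numbered 3 (0.06, 0.185). It was lost, too, with averaged probe sets (0.11, 0.0509), quantile normalisation (0.11, 0.0658), array weights (0.10, 0.0645) and no moderation (0.12, 0.133).

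Immediate early genes, transcription factors and regulators induced within minutes of stimulation, had a lower mean in 1 MG culture, while the other 2 lay within the range of PBS. The list was called, in the direction of lower values, by the preset camera test, but not with an estimated correlation or by fry. Of 25 genes, 18 had lower and 7 higher means, with a mean log2 difference of -0.14 and an adjusted p of 0.0409 (camera, Benjamini-Hochberg). The adjusted p was 0.994 with an estimated correlation and 0.9998 with fry. The members named were Arc (log2 difference -0.33), the AP-1 genes Fosl2 (-0.27) and Junb (-0.24), and Btg2 (-0.24). No member had an unadjusted p under 0.05. Per array, the list stood at 0.01, -0.05 and 0.24 in PBS, and at -0.41, -0.02 and 0.23 in MG, so that the arrays numbered 3 were the highest of their groups and MG replicate 1 was the lowest. This was 1 of 2 calls, fewer than any other split of the arrays gave. Without MG replicate 1 the mean was 0.04 (adjusted p = 0.831). The call was lost without PBS replicate 3 (mean -0.05, adjusted p = 0.281) or MG replicate 2 (-0.16, 0.0529), with array weights (-0.12, 0.0541) and with no moderation (-0.14, 0.133).

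**Figure D3:**
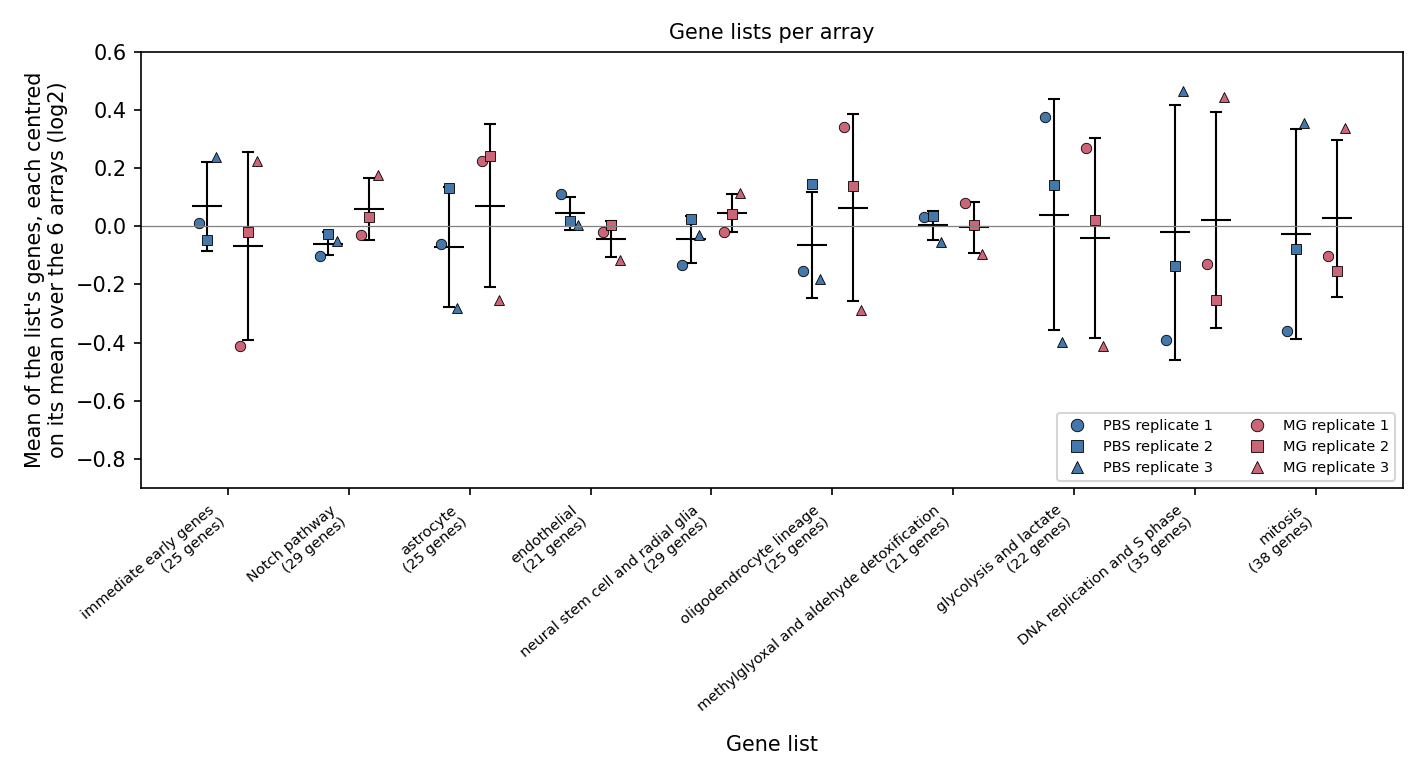
Mean of a list's genes on each array (y axis, log2, each gene centred on its mean over the 6 arrays) for 10 gene lists (x axis), with 1 point per array, colour for the group, shape for the replicate, and bars for the mean ± SD of 3 arrays. For DNA replication and S phase the arrays numbered 3 sit at 0.46 and 0.44, above the other 4 arrays.

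Most markers of astrocytes, stem cells, oligodendrocytes and neurons had higher means after MG and most endothelial markers lower ones, but no cell type list passed the adjusted test. Counts of higher and lower means, here and for the other lists, were not set against the share among all genes tested. A majority alone therefore shows no shift. Astrocyte genes came closest, with higher means in 24 of 25 genes, a mean log2 difference of 0.14 and an adjusted p of 0.0535. Of 29 neural stem cell and radial glia genes, 20 had higher means (mean log2 difference 0.09, adjusted p = 0.261). Oligodendrocyte lineage genes had higher means in 18 of 25 (0.13, adjusted p = 0.261), and neuroblast and neuron genes in 20 of 32 (0.06, adjusted p = 0.652). Genes of activated stem cells and transit amplifying cells were split, 10 higher and 8 lower (adjusted p = 0.905). Endothelial genes had lower means in 13 of 21, with a mean log2 difference of -0.09 and an adjusted p of 0.0535, but only 9 were above the reference level in both groups. With dim genes left out its mean was 0.13 over 3 genes (adjusted p = 0.735). Ependymal and motile cilia genes had higher means in 16 of 26 (adjusted p = 0.988) and pericyte, smooth muscle and fibroblast genes in 12 of 26 (0.652). Microglia and macrophage genes had lower means in 15 of 24 (0.753), and choroid plexus genes in 8 of 15 (0.753). The astrocyte list was past the threshold in 9 of 20 settings, with adjusted p from 1.8e-06 to 0.9998, and with 1 array left out its mean ran from 0.04 (without PBS replicate 3) to 0.30 (without MG replicate 3). With an estimated correlation its p was 0.420 unadjusted and 0.994 adjusted. At the preset correlation the oligodendrocyte list was past the threshold without PBS replicate 2 (0.0137), MG replicate 3 (1.4e-05) or both arrays numbered 3 (0.000308), and its mean was -0.01 without MG replicate 1. With an estimated correlation its adjusted p in these fits was 0.854, 0.848 and 0.993.

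Metabolic and stress lists had mean log2 differences between -0.09 and 0.05, and none of them passed. Genes of glycolysis and lactate had lower means in 16 of 22 (mean log2 difference -0.08, adjusted p = 0.514), heat shock genes in 8 of 12 (-0.09, 0.261), p53 response and senescence genes in 13 of 22 (-0.03, 0.779) and apoptosis regulators in 12 of 19 (-0.04, 0.410). Glutathione and NRF2 genes had higher means in 17 of 26 (0.03, 0.810), unfolded protein response genes in 13 of 21 (0.02, 0.917), oxidative phosphorylation genes in 14 of 30 (-0.01, 0.779) and cholesterol synthesis genes in 12 of 19 (0.05, 0.652). Interferon response genes were split, 16 higher and 14 lower (0.01, 0.988). At the preset correlation and without PBS replicate 3, glycolysis (-0.30, adjusted p = 3.0e-05), heat shock (-0.17, 0.0204) and p53 genes (-0.16, 0.0135) were past the threshold. Glycolysis was also past it without MG replicate 1 (-0.23, 0.0455) and without both arrays numbered 3 (-0.11, 0.0394), as p53 genes were (-0.12, 0.0394), but its mean was 0.09 without PBS replicate 1 and 0.10 without MG replicate 3, and that of p53 genes 0.05 and 0.02. With an estimated correlation none of these lists passed, at an adjusted p of 0.824 without PBS replicate 3, 0.988 for glycolysis without MG replicate 1, and 0.993 without both arrays numbered 3.

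Genes of DNA replication and S phase had higher means after MG in 28 of 35 (mean log2 difference 0.04, adjusted p = 0.891), mitosis genes in 28 of 38 (0.05, 0.713) and replication-dependent histone genes in 6 of 9 (0.13, 0.457). The S phase and mitosis means sat beside the far larger distance of the arrays numbered 3 from the rest. Without PBS replicate 3 the S phase mean was 0.28 (adjusted p = 5.3e-08 at the preset correlation), and without MG replicate 3 it was -0.17 (adjusted p = 0.00133). The adjusted p of the S phase list with an estimated correlation was 0.824 and 0.942 in these 2 fits. Among signalling lists, Wnt genes had higher means in 17 of 28 (adjusted p = 0.570), hedgehog genes in 11 of 15 (0.570), BMP and TGF-beta genes in 16 of 29 (0.891), and receptor tyrosine kinase and MAPK feedback genes in 15 of 30 (0.917). Extracellular matrix genes had higher means in 20 of 32 (0.924), DNA methylation and chromatin regulators in 19 of 33 (0.891) and imprinted genes in 15 of 29 (0.851). In 5 of the 32 lists the sign of the mean differed from camera's direction, and in 7 the sign of the median did. The 5 were the ependymal, pericyte, receptor tyrosine kinase, matrix and imprinted lists. Their means were above 0 while camera's direction was that of lower values. At an unadjusted p under 0.05, camera gave 6 lists with the preset correlation, 1 with an estimated correlation, and fry gave 0. No list passed after adjustment with either of the latter. With an estimated correlation none passed with arrays left out, the lowest adjusted p being 0.824.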

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

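Leaving out both arrays numbered 3 was chosen only after the principal components were seen, and estimating the correlation with arrays left out only after the list calls were seen. The other alternatives were chosen beforehand. The direction of a list is the sign of its mean log2 difference, a definition adopted after a first run, and its call rests on the adjusted p of the set test. No setting gave a gene past the adjusted threshold, while between 179 (dim genes left out) and 1288 (all probe sets) had an unadjusted p under 0.05. Of 514 other values of named genes, 512 kept their direction and stayed short of the threshold. That was largely set in advance. The 10 genes named per direction were picked for no overlap between groups, so leaving out an array could not turn their sign. Other variance moderation leaves the log2 difference itself unchanged. Of 639 other values of lists, 521 kept direction and side and 80 turned sign. In all, 17 lost a call and 27 gained one, of which 1 and 5 also turned sign. These counts leave out the estimated correlation with arrays left out, where 0 of 224 values passed in 7 fits (adjusted p from 0.824 to 0.999). That test has few degrees of freedom on so few arrays, so it does not exclude a shift. The cause was not tested unless the setting itself shows it.

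The looser count of 101 genes was 24 without dim genes and 436 over all probe sets, where 1.96% of those with several or no gene named were counted, against 0.370% of those with 1 gene. It was 41 without moderation, 208 without both arrays numbered 3, and between 115 (without PBS replicate 1) and 239 (without MG replicate 1) with 1 array left out, with 165 and 159 without PBS replicates 2 and 3, and 218 and 197 without MG replicates 2 and 3. The number of called lists was 2, and it was 1 with averaged probe sets and 1 with quantile normalisation, immediate early genes in both. It was 1 with array weights, astrocyte genes, where both calls were lost, and 0 without moderation, 0 with an estimated correlation, 0 with fry and 5 without both arrays numbered 3. With 1 array left out, their number lay between 0 (without MG replicate 2) and 7 (without PBS replicate 3). Calls gained at the preset correlation were astrocyte, S phase and mitosis genes without PBS replicate 1, and astrocyte, stem cell, oligodendrocyte and endothelial genes without PBS replicate 2. Without PBS replicate 3 they were glycolysis, heat shock, p53, S phase, mitosis and matrix genes, without MG replicate 1 glycolysis genes, and without MG replicate 3 S phase, mitosis, oligodendrocyte and astrocyte genes. Immediate early genes were past the threshold in 13 of 20 settings (adjusted p 1.8e-06 to 0.9998), Notch genes in 10 (0.00348 to 0.9998), and endothelial genes in 1 (0.0266 to 0.9998). Glo1 lay between -0.59 and -0.09 with 1 array left out, at -0.19 with array weights and at -0.065 without both arrays numbered 3.

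The replicate numbers were not taken to pair the samples, because the series names no covariate. The correlation of deviations, examined afterwards, was not over 0.1 in every same-numbered pair. Between arrays of the same number it was 0.218, 0.0402 and 0.447. PBS replicate 2 deviated more like MG replicate 1 (0.256) than like its own number. PBS replicate 1 deviated about equally like MG replicates 1 and 2 (0.218 and 0.234). Deviations within a group of 3 sum to 0, so these correlations are not independent of each other. With the replicate block, 0 genes passed, the looser count was 127, and 3 lists were called, the third being astrocyte genes (adjusted p = 0.00369 at the preset correlation). Without the block, an estimated correlation gave astrocyte genes p = 0.420 (adjusted 0.994), and it was not run with the block.

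With dim genes left out, list means turned to 0.0016 for detoxification, 0.016 for apoptosis, 0.021 for activated stem cells, 0.133 over 3 genes for endothelial, 0.0085 for choroid plexus and 0.0027 for BMP genes. Detoxification was at 0.00053 with averaged probe sets. Quantile normalisation gave 0.023 for microglia and 0.0031 for BMP genes. Median centring gave -0.0026 for receptor tyrosine kinase, -0.00063 for interferon and -0.0057 for imprinted genes. Array weights gave -0.0082 for glutathione, -0.0040 for unfolded protein response, 0.023 for BMP, -0.012 for receptor tyrosine kinase, -0.0092 for interferon, -0.0036 for cholesterol, -0.011 for matrix and -0.011 for imprinted genes. Without both arrays numbered 3, means were 0.0088 for detoxification, -0.015 for glutathione, 0.015 for microglia, 0.012 for BMP, -0.039 for receptor tyrosine kinase, -0.0057 for interferon, -0.039 for matrix, -0.010 for chromatin and -0.029 for imprinted genes.

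With 1 array left out, lists whose mean turned sign had these lowest and highest means. Detoxification genes ran from -0.049 to 0.038, glycolysis from -0.299 to 0.105, glutathione from -0.030 to 0.064, oxidative phosphorylation from -0.066 to 0.037, unfolded protein response from -0.027 to 0.051 and p53 from -0.161 to 0.053. S phase genes ran from -0.169 to 0.284, mitosis from -0.112 to 0.244 and histones from -0.027 to 0.234. Activated stem cell genes ran from -0.079 to 0.063, oligodendrocyte from -0.012 to 0.303, ependymal from -0.038 to 0.056, microglia from -0.046 to 0.0090, pericyte from -0.027 to 0.068 and choroid plexus from -0.083 to 0.022. Immediate early genes ran from -0.283 to 0.036, hedgehog from -0.021 to 0.123, BMP from -0.047 to 0.031, receptor tyrosine kinase from -0.043 to 0.045 and interferon from -0.010 to 0.039. Cholesterol genes ran from -0.037 to 0.108, matrix from -0.090 to 0.084, chromatin from -0.046 to 0.061 and imprinted genes from -0.030 to 0.029. Akr1a1 ran from -0.079 to 0.019. For dim genes, signal over background limits what these arrays can show, since 8455 of the tested genes were not above the reference level in both groups.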

Other observations

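The test of a Glo1 fall shared by the MG animals and the test of arrays with the same number were chosen after the result was seen, and the S100 and annexin list was written after S100a10 and S100a11 had been seen. The genes in the next paragraph were also picked after their values were seen. The copy-number test was set on 4 neighbouring genes, and its reading was limited to the 2 brighter ones once their levels were seen.

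S100a11, Cd109, Ly6e and Timp1, all above the reference level, had lower means after MG without passing the adjusted test. S100a11, a calcium-binding relative of S100a10, stood at 10.4 ± 0.25 in PBS and 9.76 ± 0.25 in MG, a log2 difference of -0.61. The membrane genes Cd109 and Ly6e differed by -0.62 and -0.71, and Timp1, an inhibitor of matrix metalloproteinases, by -0.53. Id4, a helix-loop-helix inhibitor and a member of the stem cell list, had a higher mean, 7.65 ± 0.17 against 7.08 ± 0.10, a log2 difference of 0.58. Each had an adjusted p of 0.9998 over all genes in limma. Id4 and Timp1 came closest over their own lists, with adjusted p of 0.0705 and 0.0719.

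Glo1 in MG replicate 3 was 0.99 below the mean of the other 5 arrays on the log2 scale, while those 5 had an SD of 0.07. A shift common to all genes of like level on that array is argued against, since 0.294% of them (3 of 1021) were as low. The array also stood apart on the first principal component, so a fall of Glo1 along with that difference is not excluded. A fall shared by the MG animals stays open, because the log2 difference without MG replicate 3 was -0.0927 with a standard error of 0.12, which does not separate 0 from -0.20, or 50% of the full difference. A lower copy number around Glo1 is another candidate explanation, since a duplication that includes this gene is known in laboratory mice and CD1 is outbred. The neighbouring genes in the GRCm38.p6 order had a median deviation of -0.128, but 2 of the 4 were below the reference level (Gm6402 -0.02, Dnah8 -0.21) and the others went apart (Btbd9 -0.05, 1700097N02Rik -0.76), while the next genes out, Zfand3 (-0.40) and Glp1r (-0.57), were also lower, as both and 1700097N02Rik were in PBS replicate 3, so this stays open.

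The arrays numbered 3 stood apart from the other 4 in both groups. Unequal scaling is argued against, since after quantile normalisation the first component held 45.9% of the variance and scores of 24.6 and 35.9 for these arrays. Handling shared by arrays of one number might add to it, but the lowest correlation of deviations within a same-numbered pair was 0.0402, which neither shows nor excludes this. The labels name no factor that both arrays share, so no biological explanation was tested.

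S100a10 and S100a11 might belong to a shift of their families. Camera over the other 25 S100 and annexin genes gave p = 0.108 with the preset correlation and 0.233 with an estimated one, with 14 genes lower. Their mean log2 difference was -0.04 with an SD of 0.16. Only 14 of the 25 were above the reference level in both groups, and the others could hardly show a fall. The mean argues against a shift of the size of S100a10 across these genes as a whole. It leaves open a small shift, or a shift in part of the families. An effect of the maternal injections on these 2 genes stays a hypothesis, since neither passed the adjusted test.

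The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. All 10 splits, the real one included, gave 0 genes past the adjusted threshold. In the looser count, 5 of the 10 splits gave at least the real 101 genes, and the highest other gave 510. The other splits above 101 gave 275 or more, and all kept both arrays numbered 3 together. The remaining splits parted these arrays, as the real one does, and gave between 50 and 87. They are too few to draw a conclusion from. For gene lists, the real split gave the fewest, 2, and the others gave between 3 and 12. The split with 510 genes puts PBS replicates 1 and 2 with MG replicate 1, apart from both arrays numbered 3 and MG replicate 2, and so points to a structure of the samples. Among the 17824 probe sets with several genes or none named here, 0 passed the adjusted threshold and 349 (1.96%) were in the looser count, against 87 of 23521 (0.370%) with 1 gene. Their median level was 4.86 against 5.83.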
